A study of Homo sapiens with 9 samples.

How the data were processed

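MicroRNA levels were measured in 9 libraries from the human mast cell line HMC-1, a line derived from a mast cell leukaemia. Per the labels, 3 libraries hold RNA of the cells, 3 hold extracellular RNA from the high density part of a sucrose gradient (HD) and 3 hold extracellular RNA from the low density part (LD). The design text of the series says that the cell, HD and LD libraries of a number come from the same culture, so the 3 cultures pair the libraries across the groups. The same-numbered libraries did not deviate together on the arrays: over the 9 pairs of libraries of a culture, the correlation of their deviations from the group means ran from -0.284 to 0.212, and 1 pair was over 0.1. The pairing therefore rests on the design text.

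Each library was labelled with Hy5 and hybridised to its own 1-colour array with locked nucleic acid probes, per the labels' protocols. The deposited files give 3200 spots per array, of which 1031 are blank; 15 of the miRNA probes name several miRNAs. The array scanner, its software and a genome build are not given in the sources used here, and no genome position was used. Per the file headers, the authors' columns are a raw intensity, a background-subtracted intensity and a globally normalized intensity. Set against each other, the deposited intensity columns showed that 1 background value per array had been subtracted, close to the mean of the blank spots without the highest and lowest 5%. Values had been left empty where the raw signal was not above that mean plus 2 SD, and each array had been multiplied by 1 factor that sets the median of its detected miRNA probes to 25. A table of log2 values for the whole series was deposited as well. Its columns correlated with log2 raw intensity at 0.986 to 0.998, their medians lay between 6.75 and 6.76, and it was empty for the 25 probes marked NG on an array, a mark the files do not define. It matched a quantile normalization of raw intensities with a median difference of 0.00082 log2 units, and no background had been subtracted from it.

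The comparisons used the log2 of the authors' normalized intensity. A probe counted as detected where the file gives a normalized value. The 25 values marked NG were left out, and an undetected value was set to the lowest detected value of its array, which lay between 3.26 and 3.75 on the log2 scale. The 334 probes detected on all 3 arrays of at least 1 group were tested. Blank, spike control, negative control and other control spots entered no test. Where a probe was detected on all 3 arrays of 1 group and on none of the other, the fold is a bound and is written as at least N-fold: the mean of the detected group over the mean of the array floors. For miR-17-5p, with 1 HD spot left out, it is the fold of the model, which is the smaller. Where a probe was detected on only some arrays of a group, its fold understates the change. The number of arrays is then given for the miRNAs named by the rule below. For other miRNAs it is not always given, and their folds may rest partly on floor values. Levels are given as geometric means of the normalized signal with the SD of the log2 values. The signal of a probe depends on its sequence, so levels were compared between arrays for 1 probe, and between probes only to form the list of hairpin arms described below.

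Tests were made with limma 3.58.1 in R 4.3.3, with lmFit, contrasts.fit and eBayes. The model held the 3 groups and the culture as a block. All 9 libraries shared 1 estimate of the spread per probe, with 4 residual and 6.05 prior degrees of freedom. The p-values were two-sided and measure the spread between libraries that groups and cultures leave, which includes differences between arrays. Where values were set to the lowest detected value of an array, part of that spread is the spread of these floors. Benjamini-Hochberg adjusted p under 0.05 over the 334 probes was the threshold. The comparisons were HD against cells, LD against cells, LD against HD, the mean of HD and LD against cells, and a moderated F test of any difference among the 3 groups. Standard errors of log2 changes are those of this model. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

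Before the data were examined, lists of miRNAs were fixed: let-7 and miR-98; miR-17-92 and its paralogues; the miR-15/16 family; mast cell and haematopoietic miRNAs; entries said to be fragments of other small RNAs; serum and erythroid miRNAs; epithelial miRNAs; mesenchymal, muscle, endothelial and neural miRNAs; the imprinted cluster of chromosome 14; the primate cluster of chromosome 19; GC-rich entries often bright on arrays; hairpin arms with the lower signal; and entries with a miRBase number of 1000 or above. For the hairpin arms only the rule was fixed: of each hairpin with both arms tested, the arm with the lower mean over all arrays. Its members thus come from the tested arrays and from levels of different probes, which does not show which arm is the passenger strand, so its counts are given and nothing rests on its test. The haematopoietic list shares miR-451a with the serum list and miR-126-3p with the mesenchymal list, and 3 tested entries are both fragments and GC-rich. Each list with at least 3 tested members was tested with camera at a preset correlation of 0.01, which asks whether its members changed more than the other tested probes, and p-values were adjusted over the 30 tests. Of the 30 tests 19 were called, 1 of them that of the hairpin arms in LD against cells (adjusted p = 0.0447). None of the 19 calls held with an estimated correlation within the list, where adjusted p-values were at least 0.54 and 2 of the 30 tests had an unadjusted p under 0.05.

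The rule for named miRNAs was fixed at the same time. It takes, in each comparison, the 6 largest rises and the 6 largest falls among called probes that were detected on all arrays of both groups and changed the same way in all 3 cultures. It adds the 2 largest bounds each way, the largest called rise and fall of each list except the last 2, and 10 miRNAs chosen by name. Of these 10, miR-486-5p was detected on 2 HD arrays and 1 LD array, and miR-122-5p on 1 cell array, so neither was tested. Named outside the rule, and chosen after their values were seen, were miR-1246, miR-128, miR-9-5p and miR-486-3p in HD against cells, miR-5100 and miR-1260b in LD against cells, and the miRNAs of the last part that the comparisons do not name.

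The alternatives fixed at that time were quantile normalization, scaling on the 81 probes detected on all 9 arrays, no scaling, normexp with an offset of 50 followed by quantile normalization, undetected values left missing, log2 of the value plus 1, other filters, no culture block, an intensity trend, a log2 change of at least 1 as a further threshold, the deposited log2 table, only the groups compared, the array slide as a block, and leaving out each library and each culture. Scaling on the spike control spots was added after seeing the data, as were the alternatives for the counts shared by both fractions and for LD means between those of cells and HD. Undetected values were set to the floor before the spike control scaling. A probe counted as higher on the spike controls may thus not have been detected in the fraction, and its value there is then an upper limit. The same scripts were tested on simulated data with the real probes and spreads. Of 34 probes changed by 1 log2 unit, 58.8% were recovered for HD against cells, 55.9% for LD against cells and 61.8% for LD against HD; of 33 changed by 2 log2 units, 100%, 100% and 97.0% were recovered in the same order. False calls were 3 of 89, 1 of 86 and 4 of 90.

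The chip numbers and times that the deposited arrays carry put them on 3 slides, named A to C here. All 3 cell libraries lie on slide A, the 3 HD libraries and LD library 1 on slide B, and LD libraries 2 and 3 on slide C. Slide A holds cells alone, so the slide and the change from cells to extracellular RNA cannot be told apart. LD against HD was also fitted with the slide as a block, which rests on LD library 1 against the HD libraries of its slide.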

Results

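The data are miRNA array profiles of HMC-1 human mast cells and of the RNA that the same 3 cultures released, split by a sucrose gradient into high density (HD) and low density (LD) fractions. Each group has 3 libraries. Detected miRNA probes numbered 472 ± 33.0 in cells, 302 ± 41.7 in HD and 340 ± 33.3 in LD (mean ± SD, n = 3), which is 21.8% to 25.1%, 12.6% to 16.3% and 15.0% to 18.2% of those on an array. On all 3 arrays of a group, 113 probes were detected in cells and in neither fraction, 40 in HD alone, 6 in LD alone, 73 in cells and LD, 10 in cells and HD, 11 in both fractions and 81 in all 3 groups. A probe detected on only some arrays of a group does not count for that group here, so these numbers do not show absence. Over the 334 tested probes, libraries of a group correlated at 0.947 to 0.978. Cell and HD libraries correlated at -0.0685 to 0.119, cell and LD libraries at 0.577 to 0.707, and HD and LD libraries at 0.531 to 0.641; these are correlations across probes, which are not independent replicates. The number of arrays limits the precision. All levels are relative to the median detected probe of an array, because the authors scaled each array to that median, and the amount of RNA in a fraction was not measured here.

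The comparison of HD with cells asks which miRNAs of the cell are found in the dense extracellular fraction, and at what level. Conserved families and miRNAs of blood cells were far lower in HD. So were most tested entries with a miRBase number below 1000, which include all members of these lists: 128 of 174 fell and 21 rose. The list tests below do not set these members apart from other entries numbered below 1000. let-7a-5p, of the conserved let-7 family that acts in differentiation, had a normalized signal of 1615 in cells and 16.2 in HD, a log2 change of -6.64 ± 0.37 (SE, n = 3 per group), and it was detected on 2 of 3 HD arrays. miR-21-5p, often raised in tumours, had a log2 change of -7.18 ± 0.42 and was detected on 1 HD array, as was miR-223-3p, a miRNA of myeloid cells, at -6.64 ± 0.52. miR-146b-5p, which dampens inflammatory signalling, was detected on no HD array and was at least 178-fold lower. A different set of probes was higher in HD: miR-4530 rose from a signal of 208 to 13730, 65.9-fold, and miR-642b-3p, miR-4688, miR-1275, miR-204-3p and miR-4459 rose between 27.9-fold and 36.0-fold.

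All 9 tested members of the let-7 and miR-98 list fell in HD, with a median log2 change of -5.38 (camera adjusted p = 0.00115; adjusted p = 0.54 with an estimated correlation). let-7f-5p fell by 7.10 on the log2 scale, detected on 1 HD array. HD values of this list lie at or near the detection floor, so its members cannot be ranked by their fall. The 13 tested members of miR-17-92 and its paralogues, a cluster that promotes proliferation, also all fell, with a median of -4.80 (adjusted p = 0.000253; adjusted p = 0.54 with an estimated correlation). miR-17-5p, detected on neither HD array with a usable spot, was at least 158-fold lower. All 6 members of the miR-15/16 family fell, with a median of -5.36 (adjusted p = 0.0359; adjusted p = 0.54 with an estimated correlation), among them miR-16-5p at -6.83 ± 0.58, detected on 1 HD array, but under spike control scaling 4 fell and 1 rose. The medians of these 3 families stayed negative under each scaling and normalization tried.

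Of 16 tested mast cell and haematopoietic miRNAs, 14 fell (15 adjusted over the list alone), 1 rose and 1 was not called, with a median of -4.02 (adjusted p = 0.00206; adjusted p = 0.54 with an estimated correlation). Under spike control scaling 9 fell and 3 rose. Only 3 of the 16 were detected on all HD arrays, so floor values can enter these rises. miR-142-5p, from a hairpin restricted to blood cells, fell from a signal of 414 to 15.8, by 4.71 ± 0.37 on the log2 scale, and miR-142-3p, detected on no HD array, was at least 21.8-fold lower. miR-221-3p and miR-222-3p, which target the mast cell receptor KIT, were also detected on no HD array and were at least 32.6-fold and 9.01-fold lower. The member that rose was miR-451a, a red cell miRNA, at 2.44 ± 0.86 (adjusted p = 0.0229), with 2 of 3 cell arrays and all HD arrays detecting it. That call ended without cell replicate 1 (1.51), cell replicate 3 (2.57) or HD replicate 1 (0.92), when scaled on the probes detected on all arrays (0.99), with log2 of the value plus 1 and with the wider filter. Its SD in HD was 1.78 log2 units.

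Entries whose sequence is said to lie in other small RNAs split: 8 of 13 fell, 4 rose and 1 was not called, with a median of -1.33 that was 1.56 under spike control scaling, and the list as a whole was not called (adjusted p = 0.465). Without scaling 5 fell and 2 rose, on the probes detected on all arrays 9 fell and 1 rose, and on the spike controls 5 fell and 8 rose. miR-4454 and miR-1260b, both matching parts of tRNAs, fell by 7.55 ± 0.41 and 5.90 ± 0.48 on the log2 scale, and miR-4286 fell by 8.05 ± 0.38, detected on 2 HD arrays. miR-3648 rose by 2.62 ± 0.50 and miR-1246, which matches a spliceosomal RNA, by 1.65. Of 34 GC-rich entries often bright on arrays, 21 rose and 4 fell, with a median of 1.31 (adjusted p = 0.000217; adjusted p = 0.54 with an estimated correlation); when arrays were scaled on the probes detected on all of them, 11 rose, 11 fell and the median was -0.14. On the spike controls 33 rose and 0 fell, and 1 fell both without scaling and with slide as a random block. miR-4505 fell by 2.17 ± 0.32 and miR-4508 by 1.74 ± 0.44, the latter not called without culture 2 (-1.72) or without scaling (-1.54). Among 160 entries numbered 1000 or above, 81 rose and 37 fell, with a median of 0.89 (adjusted p = 5.33e-14; adjusted p = 0.54 with an estimated correlation) that was -0.56 when scaled on the probes detected on all arrays, where 44 rose and 70 fell. Without scaling 61 rose and 18 fell, and on the spike controls 142 rose and 10 fell. Of the 19 hairpin arms with the lower signal 14 fell and 2 rose, but 1 fell and 12 rose under spike control scaling, and 7 fell and 0 rose without scaling. Only 3 of these arms were detected on all HD arrays, so the rises on the spike controls include floor values.

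Lists of other cell types had few tested members. The 3 mesenchymal, endothelial and neural members, miR-126-3p, miR-128 and miR-9-5p, all fell in HD (median -2.52, but 0.38 with 0 called under spike control scaling; adjusted p = 0.179), with miR-126-3p at least 7.09-fold lower. Of 11 epithelial miRNAs, 10 were detected on some array and 0 on all arrays of a group, so none was tested. Of the 3 tested serum and erythroid miRNAs, miR-451a rose, miR-16-2-3p, detected on no HD array, was at least 2.07-fold lower and miR-486-3p was not called (adjusted p = 0.707 for the list). The miR-16-2-3p call, at a log2 change of -1.05 against the floor, ended without cell replicate 2 (-0.78), cell replicate 3 (-0.89) or HD replicate 2 (-0.93), without scaling (-0.85), by quantile normalization (-0.66), by normexp (-0.23), in the deposited log2 table (-0.13) and with the wider filter. The chromosome 14 cluster had 2 tested members, of which miR-494 fell by 1.22 ± 0.45 on the log2 scale. That call ended without cell replicate 1 (-1.11), cell replicate 2 (-1.32), cell replicate 3 (-1.23) or HD replicate 3 (-0.65), without scaling (-1.02), by quantile normalization (-0.71), with log2 of the value plus 1 and with the wider filter. The chromosome 19 cluster had 1 tested member, not called at -0.43.

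By limma with culture as a block, 267 of 334 probes differed between HD and cells, 102 higher and 165 lower, and 65 of these were detected on all 6 arrays. The probes with the largest bound above cells were miR-1202, at least 61.5-fold, and miR-887, at least 36.7-fold; miR-1273g-3p was at least 174-fold lower. miR-24-3p, with a log2 change of -2.12 ± 0.53, was detected on all 6 arrays. The split depended on the scaling: 55 higher and 220 lower when scaled on the probes detected on all arrays, and 223 higher and 56 lower on the spike controls. The 223 include probes detected on no HD array, such as miR-16-2-3p, through their floor values. It also turned without values set to the floor. The 81 probes detected on all arrays, tested alone, gave 50 higher and 8 lower, and undetected values left missing gave 77 and 63. Under spike control scaling, chosen after seeing the data, miR-4508 and miR-494 were higher in HD. miR-4505, miR-24-3p, miR-126-3p and miR-222-3p (-0.28) were no longer called. miR-16-2-3p was also called higher (1.84), but it was detected on no HD array. Its HD value is a floor, so a rise was not shown. With slide as a random block 211 probes were called and the calls of miR-24-3p, miR-4508, miR-451a, miR-16-2-3p and miR-494 ended.

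**Figure D1:**
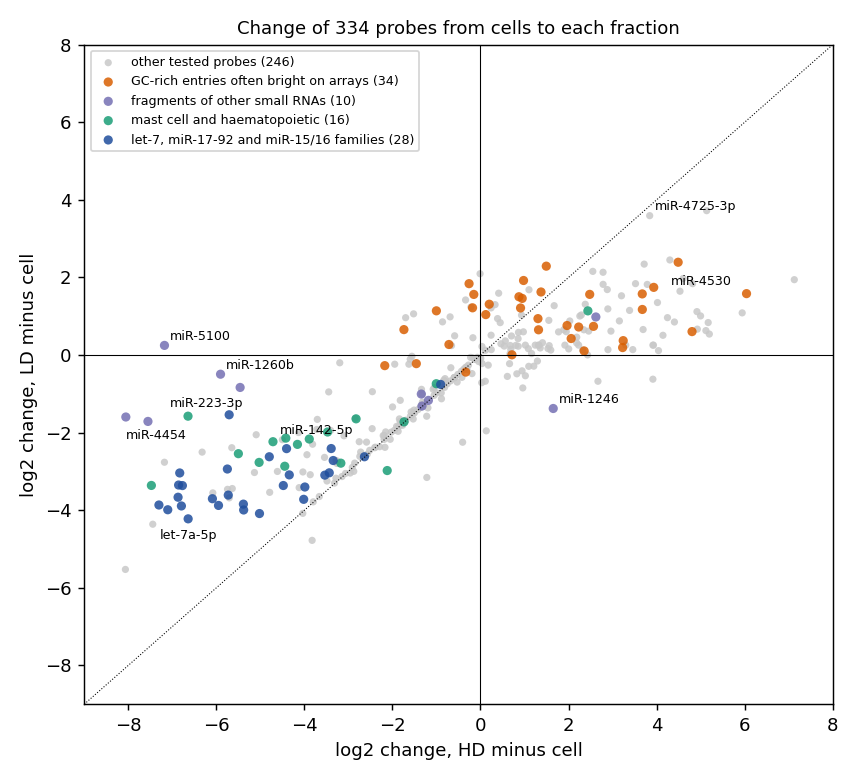
Each point is 1 of 334 probes, with its log2 change from cells to HD on the x axis and from cells to LD on the y axis; colours mark lists, with 3 entries that belong to the GC-rich and the fragment list drawn as GC-rich. With the scaling shown, members of the let-7, miR-17-92 and miR-15/16 families lie at the lower left, and the medians of these families stayed negative on both axes under each scaling and normalization tried, although 1 member of miR-15/16 was called higher on each axis under spike control scaling; points on the dotted line have equal changes, many of them at the detection floor in both fractions.

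LD was compared with the same cells to ask which cellular miRNAs are found in the light extracellular fraction. The same families were lower in LD, but most remained detectable. let-7a-5p had a signal of 86.6 in LD, a log2 change of -4.22 ± 0.37 (SE, n = 3 per group), and let-7e-5p and let-7f-5p were lower by 15.9-fold each. miR-21-5p was 6.79-fold lower and miR-16-5p 8.22-fold lower, both detected on all LD arrays. Among probes detected on all 6 arrays, the largest fall was that of miR-4284, at -5.53 ± 0.58, followed by miR-1273g-3p at -4.36 ± 0.36. Among these probes the largest rises were those of miR-4725-3p, from 20.7 to 249 (3.59 ± 0.34 log2 units), and of miR-4281, miR-4484, miR-663a, miR-4745-5p and miR-4749-5p, which were 4.39-fold to 5.25-fold higher.

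All 9 members of the let-7 and miR-98 list fell in LD (median -3.72; camera adjusted p = 0.000372; adjusted p = 0.54 with an estimated correlation). So did all 13 of miR-17-92 and its paralogues (median -3.36; adjusted p = 0.000217; adjusted p = 0.54 with an estimated correlation), with miR-20b-5p at -3.89 ± 0.37. In the miR-15/16 family 5 of 6 fell, and 6 of 6 when adjusted over the list alone (median -3.04; adjusted p = 0.0482; adjusted p = 0.544 with an estimated correlation), with miR-497-5p at -4.09 ± 0.33; the adjusted p of this list was 0.06 without the culture block, 0.0829 by quantile normalization, and 0.0512, 0.0814, 0.0711, 0.0546 and 0.05 without cell replicates 1, 2 and 3, HD replicate 3 and LD replicate 1. Each of these 3 medians stayed negative under each scaling and normalization tried, but under spike control scaling 7 of miR-17-92 and 2 of miR-15/16 fell, and 1 of the latter rose. Of 16 mast cell and haematopoietic miRNAs 14 fell, with a median of -2.20 (adjusted p = 0.00547; adjusted p = 0.54 with an estimated correlation), but the median was 0.03 under spike control scaling, where 1 fell and 2 rose. Without scaling 3 fell and 1 rose. miR-146b-5p had a log2 change of -3.36 ± 0.38, miR-142-3p -2.87 ± 0.34, miR-221-3p -2.77 ± 0.36 and miR-222-3p -2.79 ± 0.35. miR-223-3p was 2.98-fold lower (adjusted p = 0.0225), a call that ended without cell replicate 2 (log2 change -1.26), cell replicate 3 (-1.53) or LD replicate 1 (-1.09), and by quantile normalization (-0.44), by normexp (-0.40), in the deposited log2 table (-0.22) and with the wider filter. miR-451a was not called, at 1.14 ± 0.86, although it was without HD replicate 1, without scaling (2.00), under spike control scaling (3.37) and when only the groups compared were fitted.

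Of the entries said to lie in other small RNAs, miR-5100 had a signal of 2315 in LD and 1949 in cells, a log2 change of 0.25 that was not called (adjusted p = 0.543), and miR-1260b was not called at -0.49 (adjusted p = 0.399). miR-4454 was 3.27-fold lower. It was the brightest miRNA probe on every cell and LD array, so quantile normalization, normexp and the deposited log2 table give it the same top value on each and cannot show its change. In the list 6 of 13 fell, 2 rose and 5 were not called; the median was -0.83 and the mean -0.29, while camera ranked the list above the other probes without calling it (adjusted p = 0.616). The median became positive under quantile normalization (0.09), by normexp (0.09), in the deposited log2 table (0.18), without scaling (0.02) and under spike control scaling (1.39). The falls depended on the setting: 0 fell and 2 rose without scaling, 0 and 9 on the spike controls, and 0 and 1 with slide as a random block. By quantile normalization 2 fell and 5 rose, by normexp 3 and 5, with the deposited log2 values 3 and 6, and on the probes detected on all arrays 8 and 1.

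Of the 34 GC-rich entries, 18 rose in LD and 0 fell, with a median of 1.09 that stayed positive under each scaling and normalization tried (adjusted p = 8.08e-09; adjusted p = 0.54 with an estimated correlation). When scaled on the probes detected on all arrays, 5 rose and 3 fell, with a median of 0.37. With slide as a random block, 3 of 33 rose. By quantile normalization 30 rose, by normexp 29, with the deposited log2 values 28 and on the spike controls 34. Entries numbered 1000 or above had 47 of 160 higher and 23 lower, or 43 and 21 adjusted over the list alone, with a median of 0.26 (adjusted p = 5.39e-19; adjusted p = 0.54 with an estimated correlation), or -0.47 when scaled on the probes detected on all arrays, where 15 were higher and 46 lower. With slide as a random block 13 of 159 were higher and 12 lower. The counts were 38 higher and 5 lower without scaling, 77 and 16 by quantile normalization, 71 and 14 by normexp, 64 and 13 in the deposited log2 table, and 142 and 5 on the spike controls. Of the 19 hairpin arms with the lower signal 13 fell and 0 rose, but 0 fell and 8 rose under spike control scaling, and 2 fell without scaling and 8 in the deposited log2 table. Only 2 of these arms were detected on all LD arrays, so the rises on the spike controls include floor values. The 3 mesenchymal, endothelial and neural members fell (median -1.90, but 0.33 under spike control scaling; adjusted p = 0.173), with miR-128, detected on 2 LD arrays, at -2.46 ± 0.28. Of these 3, 0 were called on the spike controls and without scaling, and 1 by normexp and in the deposited log2 table. Of the 3 serum and erythroid miRNAs, 0 were called (adjusted p = 0.563), but 3 rose on the spike controls, 1 rose without scaling and 1 fell on the probes detected on all arrays. miR-494 of the chromosome 14 cluster fell by 3.16 ± 0.45 on the log2 scale, and the tested member of the chromosome 19 cluster was not called at -0.42.

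In all, 203 of 334 probes differed between LD and cells, 56 higher and 147 lower, and 106 of these were detected on all 6 arrays. Without cell replicate 2 the split was 37 higher and 132 lower, without cell replicate 3 it was 32 and 140, without culture 2 it was 29 and 128, and without culture 3 it was 31 and 140. miR-4689 and miR-3679-5p, detected on no cell array, were at least 5.47-fold and 3.22-fold higher, and miR-3175 and miR-3651, detected on no LD array, at least 27.4-fold and 16.9-fold lower. The split moved with the scaling: 92 higher and 129 lower by quantile normalization, 80 and 121 by normexp, and 71 and 117 in the deposited log2 table. It was 46 and 49 without scaling, 36 and 136 with log2 of the value plus 1, 20 and 187 when scaled on the probes detected on all arrays, and 202 and 31 on the spike controls. The 81 probes detected on all arrays, tested alone, turned it to 39 higher and 5 lower. With undetected values left missing it was 49 and 90. Named calls were lost under spike control scaling for miR-4454 (0.52), miR-223-3p (0.65), miR-21-5p (-0.53), miR-16-5p (-0.81), miR-221-3p (-0.54), miR-222-3p (-0.56), miR-142-3p (-0.64), miR-128 (-0.23) and miR-494 (-0.93). Without scaling they were lost for miR-21-5p (-1.90), miR-221-3p (-1.91), miR-222-3p (-1.93), miR-128 (-1.60), miR-223-3p (-0.72) and miR-4454 (-0.85). With log2 of the value plus 1, the calls of miR-21-5p (-2.76), miR-16-5p (-3.03) and miR-223-3p (-1.57) ended, although their changes hardly moved. With slide as a random block 135 probes were called, 17 higher and 118 lower, and the calls of miR-4454 and miR-223-3p ended.

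**Figure D2:**
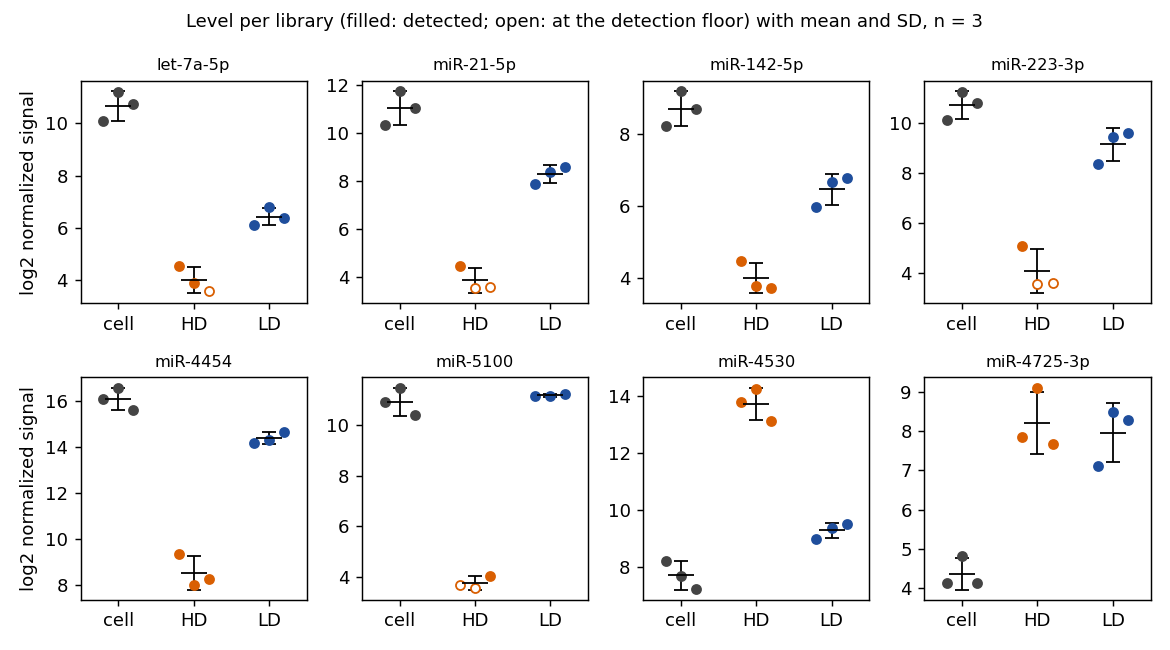
Each panel gives the log2 normalized signal of 1 miRNA in the 9 libraries, with filled points for detected values, open points for values at the detection floor, and the mean and SD of each group (n = 3). let-7a-5p, miR-21-5p, miR-142-5p and miR-223-3p were highest in cells and lowest in HD, miR-4454 fell 3.27-fold from cells to LD and 188-fold from cells to HD, miR-4530 was highest in HD, and axes differ between panels.

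LD against HD asks whether the fractions of a culture differ from each other. miR-5100 was 172-fold higher in LD, detected on 1 HD array, miR-4454 57.3-fold higher and miR-1260b 42.5-fold higher, both detected on all 6 arrays. miR-223-3p was 33.5-fold higher and miR-21-5p 21.3-fold higher in LD, each detected on 1 HD array. Higher in HD were miR-4655-5p, 36.4-fold, miR-1202, 29.0-fold, miR-575, 23.2-fold, miR-4688, 22.5-fold, miR-4530, by 4.46 on the log2 scale, and miR-642b-3p, 20.2-fold.

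Of the let-7 and miR-98 list, 7 of 9 were higher in LD and 0 lower (median 1.54; camera adjusted p = 0.00306; adjusted p = 0.54 with an estimated correlation). Of miR-17-92 and its paralogues, 10 of 13 were higher (median 2.12; adjusted p = 0.000253; adjusted p = 0.54 with an estimated correlation), and of the miR-15/16 family 4 of 6 (median 1.49 above that of all tested probes; adjusted p = 0.0411; adjusted p = 0.54 with an estimated correlation). The last of these calls ended by quantile normalization (adjusted p = 0.0624) and without HD replicate 2 (0.0847) or LD replicate 2 (0.0808). The medians of these 3 families stayed positive under each scaling and normalization tried, but 4 of the let-7 list were higher on the spike controls, and 2 of the miR-15/16 family with slide as a block. let-7d-5p was at least 11.4-fold higher, miR-17-5p, detected on neither HD array with a usable spot, at least 10.8-fold higher, and miR-15b-5p was 18.0-fold higher, detected on 1 HD array. Of the mast cell and haematopoietic miRNAs 11 of 16 were higher in LD and 0 lower, or 7 and 2 on the spike controls, with a positive median under each scaling and normalization tried (1.65 with the authors' scaling; adjusted p = 0.00124; adjusted p = 0.54 with an estimated correlation), among them miR-146b-5p at least 17.3-fold, miR-142-5p 5.58-fold, miR-221-3p at least 4.79-fold and miR-142-3p at least 2.99-fold. miR-222-3p, detected on no HD array, was not called, at a bound of 1.31-fold higher, and its sign turned under spike control scaling (-0.28). miR-451a was not called at -1.30 ± 0.86, and its sign turned without HD replicate 1 (0.21) or culture 1 (0.10). miR-222-3p was called when scaled on the probes detected on all arrays (1.12) and with log2 of the value plus 1 (4.07). miR-451a was called under spike control scaling (-1.96) and with undetected values left missing (-1.30). Under spike control scaling the call of miR-142-3p ended (0.92).

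The entries said to lie in other small RNAs had 6 of 13 members higher in LD and 2 lower (median 0.80; adjusted p = 0.0365; adjusted p = 0.555 with an estimated correlation), or 5 and 3 with slide as a block; miR-1246 was 8.17-fold lower in LD. GC-rich entries numbered 10 higher and 13 lower in LD, but 2 and 13 with slide as a block, with a median of -0.24 that turned positive under quantile normalization (0.41), by normexp (0.32), in the deposited log2 table (0.19), without scaling (0.43) and on the probes detected on all arrays (0.50); the list was not called (adjusted p = 0.479). Of this list 6 were higher and 4 lower without scaling, 17 and 13 by normexp, 16 and 10 on the probes detected on all arrays, and 4 and 16 on the spike controls. miR-4508 was 5.26-fold higher and miR-3665 and miR-4734 were 4.41-fold and 4.30-fold higher in LD. Of the entries numbered 1000 or above 33 were higher and 71 lower in LD, or 33 and 73 adjusted over the list alone (median -0.64; adjusted p = 6.02e-05; adjusted p = 0.54 with an estimated correlation), with a median of 0.02 without scaling and 0.09 on the probes detected on all arrays. Without scaling 27 were higher and 23 lower, on the probes detected on all arrays 45 and 39, on the spike controls 19 and 85, and with slide as a block 16 and 59. Of the hairpin arms with the lower signal 3 were higher and 2 lower, or 2 and 2 adjusted over the list alone, 4 and 0 on the probes detected on all arrays, 0 and 3 on the spike controls, and 1 and 0 without scaling and with slide as a block. Not called were the mesenchymal, endothelial and neural list (adjusted p = 0.479) and the serum and erythroid list (adjusted p = 0.942), whose median was 0.19 and mean -0.30. miR-126-3p was at least 2.27-fold higher in LD, a call that ended without HD replicate 2 (log2 difference 0.98), HD replicate 3 (0.89), LD replicate 2 (1.17) or LD replicate 3 (0.87), without scaling (1.84), under spike control scaling (0.52), with the wider filter and when only the groups compared were fitted. miR-494 was 3.83-fold lower in LD, and its call ended when culture 2 was left out (-1.76) and without scaling (-1.27).

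In all, 174 of 334 probes differed between LD and HD, 86 higher and 88 lower in LD, and 63 of these were detected on all 6 arrays. miR-3622a-5p and miR-3619-3p, detected on no LD array, were at least 15.2-fold and 12.8-fold lower there. Scaling on the probes detected on all arrays gave 119 higher and 53 lower, no scaling 71 and 29, and spike control scaling 52 and 107, and without culture 2 the count was 113, 60 higher and 53 lower. The 81 probes detected on all arrays, tested alone, gave 15 higher and 39 lower, and undetected values left missing gave 50 and 63. With slide as a block, 127 probes were called, 50 higher and 77 lower, all 174 kept their direction, 121 of them kept their call, and the calls of miR-4508, miR-4734, miR-126-3p and miR-142-3p ended. With that block the median of the let-7 list was 1.85 (adjusted p = 0.00299), that of miR-17-92 1.93 (adjusted p = 0.00222). That of the haematopoietic list was 1.43 (adjusted p = 0.00229), that of the miR-15/16 family 0.74 (adjusted p = 0.0827). That of the fragment list was 0.29 (adjusted p = 0.0471), that of the GC-rich list -0.70 (adjusted p = 0.0331), and that of the entries numbered 1000 or above -0.86 (adjusted p = 3.55e-06). Each of these 7 lists had an adjusted p = 0.721 with an estimated correlation. With slide as a block the log2 differences were 1.13 for miR-4508, 1.24 for miR-4734, 0.53 for miR-126-3p and 1.28 for miR-142-3p. All blocked values rest on LD library 1, which alone shares the slide of the HD libraries.

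**Figure D3:**
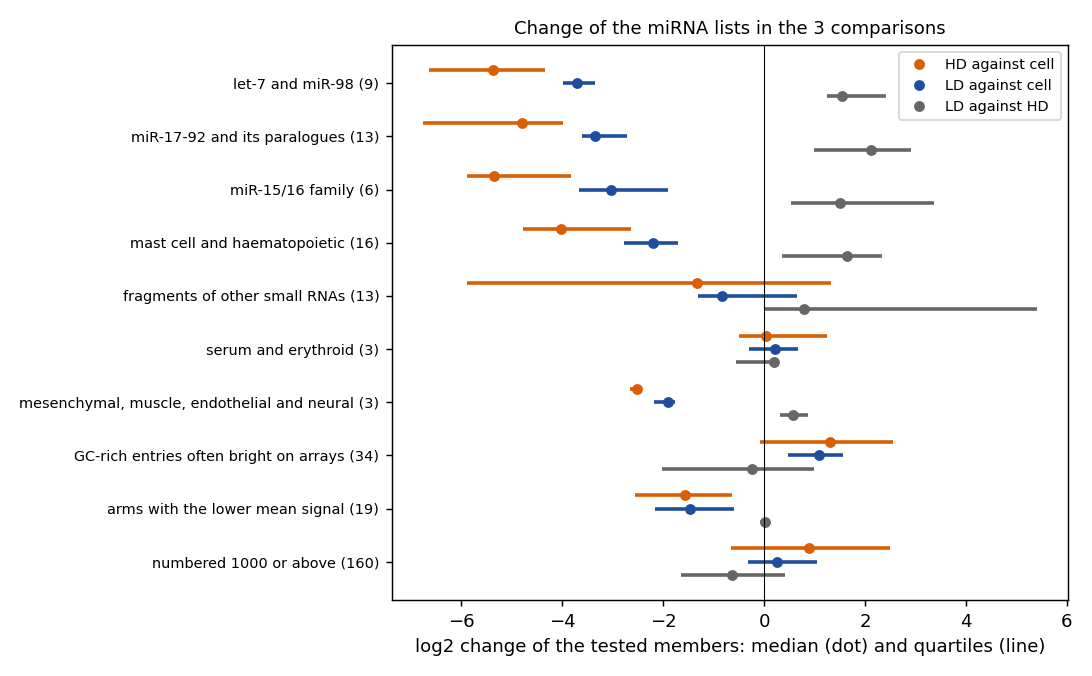
Dots give the median and lines the quartiles of the log2 change of the tested members of each list (number in brackets) in the 3 comparisons. The let-7, miR-17-92 and miR-15/16 families lie below 0 against cells and above 0 in LD against HD under each scaling and normalization tried; at least 1 of these moves the median across 0 for the haematopoietic list (LD against cells), the fragment list (both against cells), the GC-rich list (HD against cells and LD against HD), and the serum, mesenchymal, lower-signal arm and 1000 or above lists (all 3 comparisons).

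Both fractions changed largely in the same direction from cells. Lower in both were 144 probes, among them let-7a-5p and miR-21-5p, higher in both were 39, and 4 were called in opposite directions. The 2 shared counts were 177 lower and 15 higher when scaled on the probes detected on all arrays, 48 and 28 without scaling, and 26 and 194 on the spike controls, with 72 higher in both by quantile normalization and 59 by normexp. Called in opposite directions were 9 by quantile normalization, 7 in the deposited log2 table, 6 by normexp and 0 without scaling, and 0 without cell replicate 1, 1 without cell replicate 2, cell replicate 3, LD replicate 2, culture 2 or culture 3, and 2 without HD replicate 3. Higher in both were 24 without cell replicate 2, 23 without cell replicate 3 and 20 without culture 2. With the authors' scaling, independent lists of these sizes would share 72.6 lower and 17.1 higher probes. The log2 changes of the fractions correlated at 0.84 across 334 probes, against 0.49 in simulations of unchanged groups that share the same cell libraries. Their covariance was 4.47 against 0.0627 in the simulations, a difference of 4.41. With 3 cell libraries the controls could not be split with 2 in each part, so the part of the shared controls is known from the simulations alone. The simulations had no detection floor and no slide effect. In the data, 113 probes were detected on all 3 arrays of cells but not on all 3 of either fraction, and floor values can make such probes fall alike. Cells lie on a slide of their own, so the excess over the simulations cannot be told apart from a slide effect. With undetected values left missing, 181 probes remained, 43 were lower and 37 higher in both, and the changes correlated at 0.801. Among the 81 probes detected on all 9 arrays, the LD mean lay between the cell and HD means for 49, and for 42 to 62 over the scalings and normalizations tried.

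The mean of HD and LD differed from cells in 257 of 334 probes, 95 higher and 162 lower, and 278 differed among the 3 groups by the moderated F test. Scaling on the probes detected on all arrays gave 42 higher and 209 lower for the first of these counts, no scaling 85 and 105, and spike control scaling 217 higher and 50 lower. For the same count, the 81 probes detected on all arrays, tested alone, gave 51 higher and 6 lower. With undetected values left missing 66 were higher and 54 lower. Over all tested probes the median log2 change from cells to HD was -0.70, and that to LD was -0.54. These medians were -2.16 and -1.26 on the probes detected on all arrays, -0.36 and -0.22 by quantile normalization, -0.51 and 0.32 without scaling, and 2.19 and 1.69 on the spike controls. Relative to the median with the authors' scaling, the let-7 list lay at -4.68 in HD and -3.18 in LD, miR-17-92 at -4.09 and -2.82, the haematopoietic list at -3.32 and -1.66, the GC-rich list at 2.02 and 1.63, and the entries numbered 1000 or above at 1.60 and 0.80. A factor per array moves the median and the lists together and leaves these distances as they are.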

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

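The tests of scaling, of detection on the HD arrays, of the GC-rich list, of miRBase numbers and of a mixture were chosen after the results were seen. The test with slide as a block and the splits of the libraries were fixed earlier.

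miR-1246 was higher in HD than in cells (log2 change 1.65) and lower in LD (-1.38), so that LD and HD differed by -3.03 (limma adjusted p = 0.000115). The opposite held for miR-3665 (-1.0 in HD, 1.14 in LD, difference 2.14, adjusted p = 0.000366), miR-4467 (-0.86, 0.85 and 1.72, adjusted p = 0.00102) and miR-4758-3p (-1.70, 0.96 and 2.66, adjusted p = 6.48e-05), which was detected on no HD array, so that its values for HD are bounds. These 4 drew attention because the fractions changed in opposite directions from the same cells with the authors' scaling. Under spike control scaling 0 of the 4 had opposite signs; under the other scalings and normalizations all 4 did, but at most 1 of them, miR-4758-3p, was called in both. The number of probes called in opposite directions fell from 4 to 0 without cell replicate 1, to 1 without cell replicate 2, cell replicate 3, LD replicate 2, culture 2 or culture 3, and to 2 without HD replicate 3.

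Signals also appeared in spots that no comparison used. Of 22 unnamed probes of 1 series on the array, 14 were above the detection threshold on all 3 cell arrays, against 1 on all HD arrays and 1 on all LD arrays. Of the 72 negative control spots, 19 were above the threshold on the HD arrays, against 1 on the cell arrays and 5 on the LD arrays, while 5.2% to 7.3% of blank spots were above it on every array. Of these 19 spots, 14 belonged to 1 of the 3 kinds of negative control.

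The probes higher in HD than in cells number 102, among them miR-4530, and 81 of them lie outside the GC-rich list. If the authors' scaling alone had made these 102, another scaling should leave 0 of the 334 probes higher in HD. The fewest called higher under any scaling or normalization tried was 55, on the probes detected on all arrays. A scaling that centres the arrays must leave some probes higher where changes spread this widely, so that count decides nothing. Without scaling 76 were called higher, and on the spike controls 223. Of the 102, 54 were called under all scalings and normalizations tried. For the other 48 the scaling cannot be told apart from a change, since it ends their call. Signal raised by the median rise of the 102, 185 normalized units, on every spot that carries a probe would put most miRNA probes of the HD arrays above the detection floor. At most 16.3% were detected, and a rise shared by the blank spots is subtracted as background. This does not bear on a rise that differs between probes. The third kind of negative control was above the threshold on 14 of 24 HD spots, against 1 of 24 cell spots and 4 of 24 LD spots. What stays open is binding of other RNAs to GC-rich probes, which cannot be told apart from release of these miRNAs, because no probe sequence was used: 21 of 34 GC-rich entries and 81 of 300 others were higher (Fisher's exact test, two-sided p = 0.000104), as either account would have it. The slide, which holds cells alone, and a difference in what the dense fraction holds, which the design names, stay open as well and were not tested.

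Among the 81 probes detected on all 9 arrays, LD levels lay between those of cells and HD for 49 (42 to 62 over the scalings and normalizations tried), so LD may be a mixture of cellular RNA and HD material. Where HD adds little, at 3 or more log2 units below LD, a mixture would put every probe at 1 common distance from cells. The distances spread more than that: among 13 such entries numbered below 1000 their SD was 2.18 times the standard error of 1 probe, from let-7f-5p at -3.99 to miR-15b-5p at -1.54, and among 6 numbered 1000 or above 4.08 times, from miR-1273g-3p at -4.36 to miR-5100 at 0.25. The standard error holds only the spread within groups. Cells lie on a slide of their own, and with slide as a random block the correlation within a slide was 0.511. Slide differences that vary by probe could therefore also spread these distances. The values cannot decide on a mixture of the 2 for either class, and a mixture with a further component was not tested.

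LD and HD libraries lie partly on different slides. If the slide had made their differences, few would keep their direction with slide as a block, but 174 of the 174 called probes did. This argues against the slide as the whole cause for LD and HD, but the blocked value rests on LD library 1, which also entered the unblocked one; 121 of the probes kept their call. Cells lie on a slide of their own, so for cells against either fraction slide and group cannot be told apart.

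Other splits of the libraries were counted for each comparison. For HD against cells, LD against cells and LD against HD, 1 of 10 splits of the 6 libraries, the real one, called as many probes (267, 203 and 174); the highest of the others called 0, with at most 3, 6 and 14 probes at an unadjusted limma p under 0.05, the 3 other splits that part all 3 cultures included. The remaining 6 of each comparison part 1 culture. With 10 splits the share is never under 0.1, which is too few to go further. For the mean of HD and LD against cells, 1 of 100 drawn splits of the 9 libraries, the real one, called 257, and the highest other called 175; for any difference among the 3 groups 1 of 100 called 278, and the highest other 145. Of the drawn splits, 19 coincided with a culture and were fitted without the culture block. In every split the tested probes were those chosen by detection in the real groups, which favours the real split. The drawn splits also moved libraries between groups without regard to culture. The real split thus ranked first for both fractions against cells and for any difference, but this does not exclude chance.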

How the results depend on the processing

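The alternatives were fixed before the data were examined, except spike control scaling, leaving out a library for the lists, and the alternatives for the counts shared by both fractions and for LD means between those of cells and HD, which were chosen after seeing the data. Counts of called probes are given in the order HD against cells, LD against cells, LD against HD, both fractions against cells, and any difference among the groups. Quantile normalization, normexp, the deposited log2 table, scaling on probes seen on all arrays, log2 of the value plus 1, the wider filter, the intensity trend, the fold threshold (not applied to the F test) and the fits of 2 groups left every total within 1.5 times the main one. The splits into higher and lower moved more. Higher in HD than in cells were 102 in the main fit and 55 when scaled on probes seen on all arrays. Higher in LD than in cells were 56 in the main fit, 20 with that scaling and 92 by quantile normalization. No replicate block gave 267, 201, 170, 262 and 278; among lists it ended the call of the miR-15/16 family in LD against cells. Without scaling 95 and 100 probes were called in LD against cells and LD against HD, and the cause was not tested. Undetected values left missing gave 140, 113, 120 and 141 (without LD against cells, 139, within 1.5 times), with fewer probes tested. The 81 probes detected on all arrays gave 58, 44, 54, 57 and 69, again with fewer probes. Their splits differed from the main ones: 50 higher and 8 lower in HD against cells, 39 and 5 in LD against cells, and 15 and 39 in LD against HD. Both fractions against cells gave 51 higher and 6 lower. With undetected values left missing, HD against cells gave 77 higher and 63 lower. With slide as a random block (correlation 0.511) LD against cells gave 135. Leaving out each library or culture gave 227 to 274, 157 to 212, 113 to 179, 213 to 261 and 237 to 284, the lowest each time without culture 2. Of the 19 list calls, 0 held by camera with an estimated correlation, 17 by quantile normalization, 18 with no block, and 17 to 18 when a library was left out. For named miRNAs, 1038 values with a library or culture left out stayed on their side of the threshold, 29 lost the call and 1 gained it. Among these, 0 called values changed sign, and miR-451a in LD against HD, not called, turned positive without HD replicate 1 (0.21) or culture 1 (0.10). With the other alternatives fixed beforehand 1116 stayed on their side, 44 lost the call and 5 gained it, and 0 changed sign, though 3 of them, all of miR-4454 in LD against cells, were 0. Spike control scaling reversed the sign of miR-4505 (0.72), miR-24-3p (0.77), miR-4508 (1.15), miR-16-2-3p (1.84), miR-126-3p (0.067) and miR-494 (1.67) in HD. It did so for miR-4454 (0.52) and miR-223-3p (0.65) in LD against cells, and for miR-222-3p (-0.28), not called, in LD against HD. It differs from the authors' scaling by 1 factor per array. All log2 changes of a comparison therefore move by the same amount, apart from probes with a spot left out. These reversals are thus not particular to the miRNAs named. miR-16-2-3p, miR-126-3p and miR-222-3p were detected on no HD array. Why the spike controls differed between the groups was not tested. Signal over background limits HD most, where 202 of the 267 called probes were not detected on all 6 arrays.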

Other observations

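The test of entries said to lie in other small RNAs and the arm pairs below were chosen after the data were seen.

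Arms of the same hairpin went opposite ways in HD. Among 19 hairpins with both arms tested, 4 had both arms called in opposite directions in HD against cells, 0 in LD against cells and 3 in LD against HD. miR-423-5p rose from a signal of 21.1 in cells to 134 in HD (log2 change 2.67, adjusted p = 5.32e-05), while miR-423-3p was detected on all cell arrays and on no HD array (at least 8.85-fold lower, adjusted p = 1.71e-06). miR-92b-5p rose by 2.43, miR-652-5p by 1.10 and miR-4758-5p, detected on 2 cell arrays, by 1.41 on the log2 scale. Their other arms were detected on no HD array: miR-92b-3p, of the miR-17-92 paralogues, was at least 10.5-fold lower, miR-652-3p at least 9.51-fold and miR-4758-3p at least 3.25-fold. miR-125a-5p, detected on no HD array, was at least 2.32-fold higher in LD than in HD and miR-125a-3p lower (-1.84). In LD, where 0 pairs were called in opposite directions, miR-423-5p was not called against cells (-0.68). The difference between the arms of a hairpin does not depend on a factor per array, but the direction of each arm can: such factors moved the median of all tested probes in HD against cells between -2.16 and 2.19.

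With the authors' scaling, a set of 14 probes was higher in LD than in both cells and HD. miR-4734 was the furthest above cells, at 2.10 log2 units (adjusted p = 0.000527), and lay 2.10 above HD; miR-1915-3p lay 1.84 above cells and 2.10 above HD, and miR-3656, said to lie in ribosomal RNA, 1.56 and 1.71. Lower in LD than in both were 5 probes: miR-1246, miR-125a-3p, miR-3175, miR-378f and miR-494. miR-642a-3p and miR-642b-3p, with related names, changed unequally: miR-642b-3p rose by 5.17 in HD and miR-642a-3p by 1.10, and in LD the former was not called (0.84) while the latter rose by 1.68.

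Among probes lower in HD that stayed detected in LD, entries that match other small RNAs may be kept in LD more than other miRNAs. Listed entries lost from LD did not enter this comparison. miR-3676-3p and miR-3687 of the list were detected on all cell arrays and on no HD or LD array. They were at least 2.49-fold and 2.25-fold lower in LD than in cells. Among 78 probes lower in HD and detected on all cell and LD arrays, the 5 listed entries (miR-4454, miR-1260a, miR-1260b, miR-4286 and miR-5100) had a mean log2 change from cells to LD of -0.88 (SD 0.811) and the 73 others of -2.30 (SD 1.47), a difference of 1.42 (exact permutation test over probes, two-sided p = 0.034). Probes are not independent replicates, and 5 of the others lay above miR-5100, the highest listed entry, so this stays a hypothesis.

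The spike control spots were not level between groups. Their median background-subtracted signal was 12600, 6380 and 4760 on the cell arrays 1 to 3, 1570, 399 and 2250 on the HD arrays and 1310, 3500 and 4860 on the LD arrays. What these controls were added to is not given in the sources used here.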
